A study of Caenorhabditis elegans with 3 samples.

How the data were processed

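Feeding RNAi was started in larvae of the first stage at 24 °C, and the gonads of their young adult progeny were dissected at the bend of the gonad arm into a lysis reagent, per the labels' protocols. Each replicate pooled 400 to 500 germlines and gave 1.5 to 4 µg of total RNA. Poly(A) RNA was made into libraries with a kit that does not mark strand and sequenced as single 100 bp reads, per the labels' protocols. Reads from overlapping or antisense genes could therefore not be told apart. The submitters' processing notes name CASAVA, TopHat2 2.0.8b, SAMtools 0.1.18, HTSeq 0.5.4p3 and DESeq 1.1.2.1. The genome build and gene annotation were not given in the sources used here. The labels describe 3 samples, 1 per group, and the deposited table has 12 columns whose names give the group and the replicate orig, 1, 2 or 3. The meaning of orig was not given. The series design calls the 4 libraries of a group biological replicates. The labels of the P granule group cite a reference for the RNAi; its targets pgl-1, pgl-3, glh-1 and glh-4 were taken from what is known of the study.

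The deposited table holds a normalised signal per gene and library: reads divided by a size factor of the library, which the authors computed, per the values. Every value in all 12 libraries, 187342 values above 0, was a whole multiple of the smallest value of its column within 0.01 reads (100%), so whole reads were recovered. The tests had been designed for counts, as edgeR with TMM factors. Once the deposited values were seen to be normalised, limma on log2(value + 1) was taken as the test in its place. The planned edgeR test was run on the recovered reads as an alternative. It called 1591 genes for csr-1 RNAi, 7 for P granule RNAi and 1023 between the RNAi groups. The authors also deposited, for each RNAi group, a table with group means of the same normalised signal, a fold change given as a ratio of those means, and p-values with adjusted p-values from DESeq, per the file headers. Their control means equal the means of the 4 control columns within 5e-05 reads. The tables were used as deposited. Columns of values that were not used numbered 0.

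Of 45836 gene entries, 45370 (98.98%) were matched to a gene of the WBcel235 annotation, which was used only for gene names, chromosomes and neighbours. A further 5 entries that name no gene stayed out of library sizes and tests. Of these, reads with no unique alignment made up 2.04% to 2.21% in the controls, 2.18% to 2.38% under P granule RNAi and 2.30% to 2.76% under csr-1 RNAi. Ambiguous reads made up 0.78% to 0.92% and reads in no gene 0.01% to 0.02%. The reads in genes ranged from 18.4 to 31.9 M (megareads) per library. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 14.6 or more), so each library counted once.

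Genes with a value of at least 10 in at least 4 libraries were kept, 11345 in all. limma 3.58.1 in R 4.3.3, with a trend and robust moderation, was fitted to all 12 libraries with a mean per group, and p-values were adjusted by Benjamini-Hochberg per comparison over all genes, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of genes with few reads. All adjusted p-values of single genes are limma's unless another tool is named, and edgeR is with TMM factors unless stated. Simulated libraries with 200 changed genes were used to test the procedure. For csr-1 RNAi against the control (11117 genes) it recovered 35% of 2-fold and 70% of 4-fold changes with 7.1% false calls. For P granule RNAi (11147 genes) it recovered 31% and 72% with 2.8% false calls. The simulated genes were drawn independently, without the variation that genes of a library share. These shares of false calls therefore do not describe the real libraries.

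The 20 gene lists were fixed before the data were examined: the RNAi targets, 3 sperm lists, and germline, somatic, stress, apoptosis, ribosomal and mitochondrially encoded genes. Genes of chromosome X formed a further list by plan. The mitochondrially encoded list had 0 measured genes and no result. The list of RNAi targets had a median of −2.22 under P granule RNAi (camera adjusted p = 7.21e-13, and adjusted p = 0.0486 with an estimated correlation) and of 0.07 under csr-1 RNAi (adjusted p = 0.595). In csr-1 RNAi 3 of its 5 genes were called, also adjusted over the list alone. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists and both comparisons with the control, and again with an estimated correlation and with fry. These tests ask for a shift of a list in 1 direction. fry's mixed test, given for csr-1 RNAi, asks whether members of a list changed in either direction. It does not compare the list with other genes. Under csr-1 RNAi 1677 of all 11345 tested genes were called, so a pass does not set a list apart. The mean log2 level of each list per library was compared by two-sided exact permutation over 70 arrangements, whose smallest p is 0.0286, adjusted over 22 lists: those with measured genes, all sperm lists together, and the autosomes. An adjusted p under 0.05 would need many lists at that smallest p. An adjusted p above 0.05 is thus no evidence that a list did not change. This test of library means, the correlations with cuticle genes and the combined sperm list were chosen after the data were seen.

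Single genes were named by a rule fixed before the data were examined: the RNAi targets, the 6 largest changes each way among called genes with a mean of at least 2 CPM and all 4 RNAi libraries beyond all 4 controls (5 each way for the direct comparison), and 2 called members per list with the smallest adjusted p (3 for sperm function, sex determination and oogenesis). Other genes, named where a count was 5 or fewer or where they passed adjusted over the list alone, were chosen after their values were seen. The alternatives were edgeR 4.0.16 with RLE factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM, only the groups compared, an absolute log2 fold change of at least 1, the replicate number as a block, and each library left out in turn. The planned edgeR test with TMM factors also served as an alternative. Added after the data were seen were limma with TMM factors, pseudocounts of 0.5 and 5, and 3 libraries per group without those named orig. Fits of the cuticle covariate with libraries left out and camera with an estimated correlation in each setting were also added then. So were sperm genes against other cell types, and a minimum control mean of 10 reads for the levels of genes that changed at least 4-fold. RLE factors for the lists would have repeated the deposited size factors, so TMM factors took their place. No scaling moved the median log2 fold change of all genes by over 0.1. Chance overlap between the RNAi comparisons was taken from 100 simulations of unchanged groups drawn from a normal distribution with the covariance of the residuals within groups, a form chosen after a first form, which reshuffled residuals, had proved degenerate. Figures were drawn with matplotlib 3.10.9.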

Results

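Poly(A) RNA was sequenced from gonads dissected out of young adult Caenorhabditis elegans hermaphrodites of the wild-type strain that had been fed bacteria making double-stranded RNA. The 3 groups were an empty vector control, RNA interference (RNAi) against csr-1, and a combined RNAi against P granule components. csr-1 encodes a germline Argonaute that carries small RNAs antisense to most germline-expressed genes. P granules are RNA and protein condensates at the nuclear pores of germ cells. The series describes 4 biological replicates per group, named orig, 1, 2 and 3, each from 400 to 500 germlines. The reads assigned to genes came to 29.8, 24.4, 26.2 and 23.2 M (megareads) in the control libraries orig, 1, 2 and 3. They came to 30.1, 21.8, 22.9 and 18.4 M in the P granule RNAi libraries and to 31.9, 19, 24.6 and 22.3 M in the csr-1 RNAi libraries. In all, 11345 genes passed the low-value filter and were tested.

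The RNAi targets were examined first. csr-1 had 23553 ± 1583 normalised reads in the control libraries and 3836 ± 1565 under csr-1 RNAi (SD, n = 4), a log2 fold change of −2.70 (SE 0.22, limma adjusted p = 3.56e-05). pgl-1 and pgl-3 encode the scaffold proteins of P granules. Under P granule RNAi pgl-1 fell from 20905 ± 3894 to 2218 ± 529 reads (log2 fold change −3.25, SE 0.19, adjusted p = 3.01e-06) and pgl-3 from 12102 ± 1719 to 1931 ± 304 (−2.65, SE 0.15, adjusted p = 3.01e-06). glh-4, which encodes a germline RNA helicase of the Vasa family, fell from 7145 ± 1213 to 1515 ± 66.3 (−2.22, SE 0.16, adjusted p = 1.97e-05). Its relative glh-1 had 24978 ± 5555 reads in the control and 17104 ± 1133 under P granule RNAi, a log2 fold change of −0.52 (SE 0.16) that did not pass the test over all genes (adjusted p = 0.299). All 4 csr-1 RNAi libraries lay below all 4 controls for csr-1, and all 4 P granule RNAi libraries did so for pgl-1, pgl-3 and glh-4. For glh-1 3 of the 4 did. Adjusted over the list alone, all 5 target genes were lower under P granule RNAi, csr-1 included (15509 ± 1075 reads, log2 fold change −0.60, SE 0.22, adjusted p = 0.317 over all genes).

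**Figure D1:**
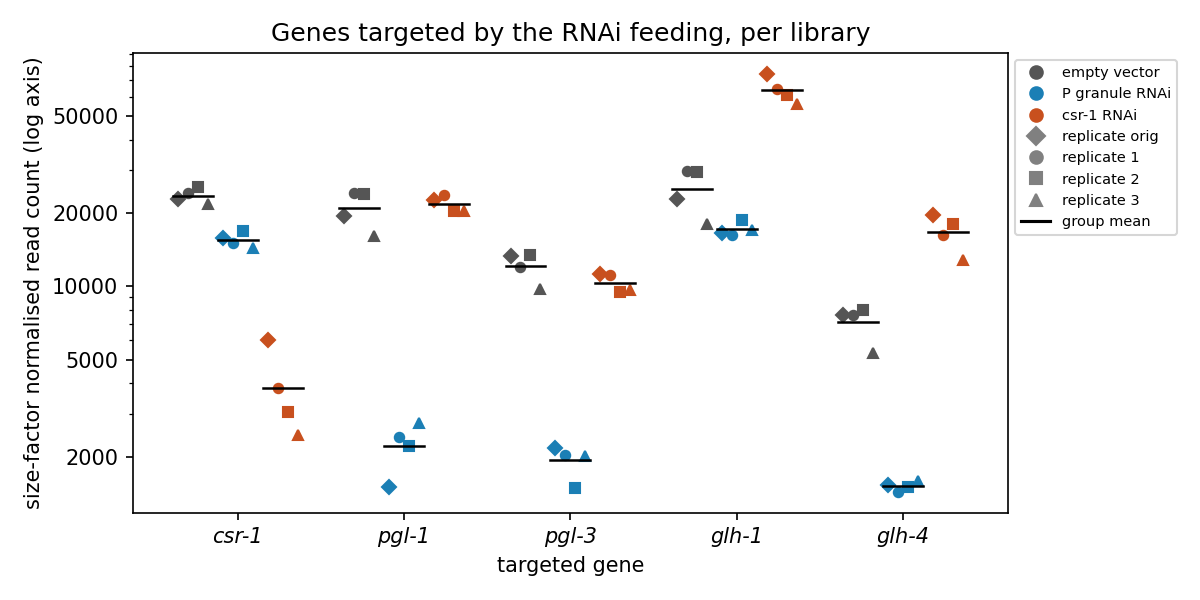
Normalised read counts (log axis) of the RNAi target genes csr-1, pgl-1, pgl-3, glh-1 and glh-4 in each library of the empty vector, P granule RNAi and csr-1 RNAi groups; points are libraries and bars group means. csr-1 averaged 3836 reads under csr-1 RNAi against 23553 in the control, and pgl-1 averaged 2218 under P granule RNAi against 20905.

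The comparison of csr-1 RNAi with the empty vector asks which germline transcripts depend on this Argonaute. Transcripts of 2 other P granule genes moved up: glh-1 rose to 63969 ± 7750 reads (log2 fold change 1.38, SE 0.16, adjusted p = 0.000326) and glh-4 to 16674 ± 2890 (1.22, SE 0.16, adjusted p = 0.000556). pgl-1 (0.07, SE 0.19) and pgl-3 (−0.22, SE 0.15) did not pass the test. In all, 1677 genes were called, 792 higher and 885 lower (limma, 4 libraries per group), and 839 of them had an absolute log2 fold change of at least 1, 438 higher and 401 lower. Which direction held more genes depended on the method: DESeq2 called 1422 higher and 1080 lower, edgeR with TMM factors 838 and 753 and with RLE factors 862 and 781, and limma without the low-value filter 844 and 705. The count depended on single libraries: it was 1064 without control replicate 1, 931 without control replicate 2, 1036 without csr-1 replicate 1 and 1021 without csr-1 replicate 2. The P granule component list, which leaves out the RNAi targets, had 5 of 27 members higher and 3 lower, as it did adjusted over the list alone. The list as a whole did not shift in 1 direction (median log2 fold change −0.14, camera adjusted p = 0.5). fry's mixed test, for changes either way, passed (adjusted p = 2.45e-07), but it does not compare the list with other genes. mip-1, which encodes a scaffold protein of these granules, rose from 4451 ± 184 to 8902 ± 278 reads (log2 fold change 1, SE 0.10, adjusted p = 8.41e-05), and cgh-1, which encodes a DEAD-box RNA helicase, fell from 108720 ± 13750 to 60711 ± 3444 (−0.83, SE 0.14, adjusted p = 0.00264).

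nhr-11, which encodes a nuclear hormone receptor, rose from 20.3 ± 4.61 to 785 ± 194 reads (log2 fold change 5.20, SE 0.25, adjusted p = 8.49e-07), and rol-3, a receptor tyrosine kinase gene, from 6.85 ± 2.01 to 277 ± 106 (5.12, SE 0.42, adjusted p = 3.66e-05). The glutamate receptor gene glr-2 (4.60, SE 0.54), droe-4 (4.53, SE 0.40), Y45F3A.4 (4.18, SE 0.28) and unc-31, which encodes a factor for dense-core vesicle release in neurons (4.17, SE 0.45), completed the 6 largest rises. Their adjusted p lay between 1.15e-05 and 0.000318. The 6 largest falls were cutl-10, a cuticlin-like gene (−3.78, SE 0.65), the cadherin gene cdh-3 (−3.48, SE 0.54), noah-1, which encodes a protein of the apical extracellular matrix (−3.10, SE 0.66), bath-13 (−3.04, SE 0.39), C04G6.6 (−2.92, SE 0.23) and attf-5, which encodes an AT-hook protein (−2.92, SE 0.47). Their adjusted p lay between 3.42e-05 and 0.00852. C04G6.6 went from 423 ± 75.3 to 54.4 ± 6.15 reads. Each of these 12 genes had all 4 csr-1 libraries beyond all 4 controls, which the rule for naming them required.

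Among 29 measured genes of germline sex determination, 5 rose and 8 fell under csr-1 RNAi, or 7 and 10 adjusted over the list alone. fog-3, which is required for germ cells to become sperm, rose from 30.6 ± 12.1 to 292 ± 92.6 reads (log2 fold change 3.23, SE 0.34, adjusted p = 0.000169). her-1, a secreted male-promoting signal (2.55, SE 0.43), tra-3, a calpain gene that promotes female fate (1.25, SE 0.15), mag-1, whose loss masculinises the germline (0.81, SE 0.19), and fog-2, which permits spermatogenesis in hermaphrodites (0.51, SE 0.12), also rose. laf-1, an RNA helicase gene whose loss feminises animals, fell from 7084 ± 885 to 3891 ± 240 reads (−0.86, SE 0.13, adjusted p = 0.00142). fem-3 (−0.56, SE 0.15, adjusted p = 0.0298) and cpb-1 (−0.82, SE 0.19, adjusted p = 0.0141), both needed for spermatogenesis, fell as well. The other 5 that fell were elt-1 (−1.86), daz-1 (−0.82), gld-1 (−0.76), nos-3 (−0.76) and atx-2 (−0.75). The list as a whole did not shift in 1 direction (median −0.07, mean 0.02, camera adjusted p = 0.5). fry's mixed test, for changes either way, passed (adjusted p = 2.96e-08). It does not compare a list with other genes, and 1677 of all 11345 tested genes were called. Of 39 oogenesis genes, egg-4 (1.11, SE 0.23) and egg-5 (0.72, SE 0.20) rose and 4 genes fell, the same counts as adjusted over the list alone. egg-4 and egg-5 are a near-identical pair that can share reads, so their values are uncertain. Those 4 were meg-2 (−0.97, SE 0.19, adjusted p = 0.00654), cbd-1, which encodes an eggshell protein (−0.64, SE 0.16, adjusted p = 0.0198), meg-1 (−0.62, SE 0.17) and lin-41 (−0.55, SE 0.17). The call on cbd-1 was lost without control replicate 1 (adjusted p = 0.0505) or control replicate 2 (adjusted p = 0.0688). The oogenesis list did not shift as a whole in 1 direction (median −0.08, camera adjusted p = 0.409), and fry's mixed test gave adjusted p = 0.0153.

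Sperm genes were higher on average in the csr-1 RNAi group, with a wide spread between its libraries. All 28 measured major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, had positive fold changes (median 1.54, camera adjusted p = 0.00342), as did all 24 members of the small sperm protein families (median 1.77, camera adjusted p = 0.000266) and 30 of 32 genes of sperm function (median 1.41, camera adjusted p = 0.000266). With an estimated correlation none of these calls held, at adjusted p = 0.81 for the major sperm proteins, 0.796 for the small families and 0.785 for sperm function. Only spe-6, a casein kinase gene needed in spermatocytes (204 ± 41.9 to 778 ± 50.2 reads, 1.95, SE 0.16, adjusted p = 3.66e-05), and spe-47 (1.64, SE 0.49, adjusted p = 0.0417) passed limma's test among the 84 sperm genes, and only spe-6 adjusted over the list alone. At an unadjusted p under 0.05 there were 12 of the 84, and edgeR called 6 and DESeq2 47. Over the 84 genes the mean log2 level was 5.65 ± 0.85 in the control and 7.09 ± 2.04 under csr-1 RNAi (SD, n = 4, two-sided exact permutation p = 0.314, adjusted 0.768 over 22 lists). The csr-1 libraries orig, 1, 2 and 3 stood at 4.67, 6.23, 8.26 and 9.20, so that orig lay below all controls. Without csr-1 replicate 3 the median of the major sperm proteins was 0.64 and its call was lost (adjusted p = 0.267). The call on spe-47 was lost without any of control replicates 1, 2 or 3 or csr-1 replicates orig, 2 or 3 (adjusted p between 0.055 and 0.111), without the 3 libraries named orig (0.0504) and without the low-value filter (0.0528). Members of the major sperm protein family share nearly identical sequences, so their single-gene values are uncertain.

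Cuticle and hypodermis genes, markers of another tissue, followed the sperm genes from library to library. Across the 12 libraries, after the group means were taken out, the mean level of 98 cuticle genes correlated with that of the sperm genes (Pearson r = 0.84, permutation p = 0.0128, adjusted 0.0394 over 4 relations; Spearman rho = 0.84, permutation p = 0.019), and r was 0.88 without the 2 libraries farthest from the median. In the same family the oogenesis genes went the other way (r = −0.55, permutation p = 0.0197, adjusted 0.0394; rho = −0.73, permutation p = 0.0107; r = −0.51 without the 2 farthest libraries). Intestine genes (r = −0.32, permutation p = 0.197; rho = −0.41, permutation p = 0.174) and ribosomal protein genes (r = 0.66, permutation p = 0.106; rho = 0.49, permutation p = 0.189) did not pass, and the ribosomal r was 0.01 without the 2 farthest libraries. The mean level of the 9900 autosomal genes was not among these relations, but within groups it varied in nearly the same order as the sperm level. It was 8.13, 8.22, 8.41 and 8.37 in the csr-1 libraries orig, 1, 2 and 3. In the controls it was 8.24, 8.18, 8.03 and 8.04, and under P granule RNAi 8.29, 8.13, 8.37 and 8.28. So the relation is not particular to cuticle genes. The cuticle levels were 3.95, 4.66, 6.70 and 6.92 in the csr-1 libraries orig, 1, 2 and 3 and 6.76, 6.36, 4.66 and 4.84 in the controls. The mean cuticle level was 5.56 ± 1.48 under csr-1 RNAi and 5.65 ± 1.06 in the control (SD, n = 4, exact permutation p = 0.857). Without the 3 libraries named orig these means were 6.10 and 5.29, and the cuticle list passed camera under csr-1 RNAi (median 0.65, adjusted p = 0.00642, and adjusted p = 0.83 with an estimated correlation).

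**Figure D2:**
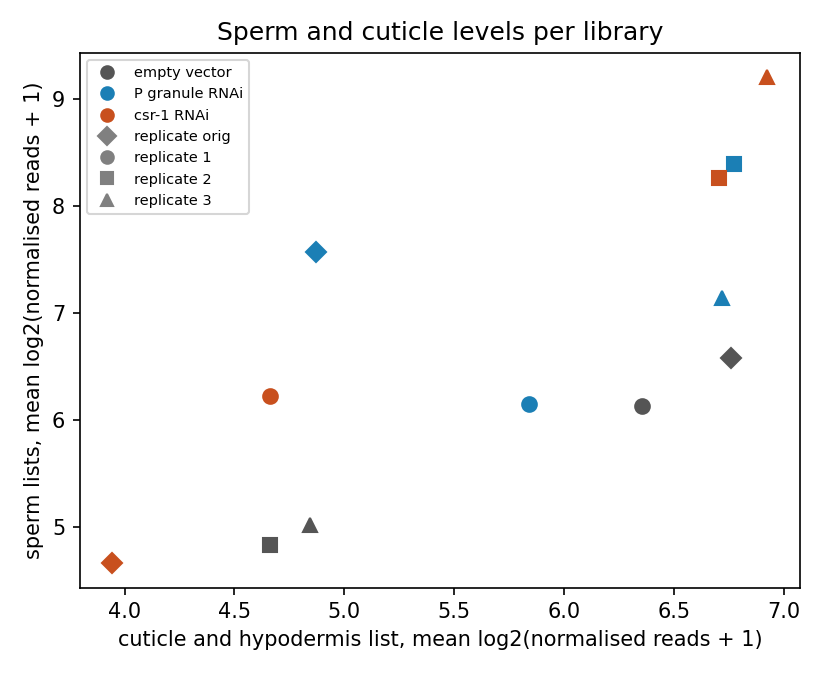
Mean log2 level of the 84 sperm genes (vertical axis) against that of the 98 cuticle and hypodermis genes (horizontal axis), 1 point per library, coloured by group. After the group means were taken out, Pearson r was 0.84 over the 12 libraries; P granule replicate orig, at 7.57 for sperm and 4.87 for cuticle genes, departed from the relation.

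Other germline gene groups had members that moved in both directions under csr-1 RNAi. fry's mixed test passed for the small RNA (adjusted p = 2.96e-08), histone (7.81e-05), meiosis (0.000254), proliferation (5.59e-08) and apoptosis (1.22e-06) lists. With 1677 of all 11345 tested genes called, these passes do not set the lists apart from other genes. Of 47 genes of small RNA pathways, 6 rose and 10 fell (6 and 14 adjusted over the list alone), csr-1 itself among those that fell. alg-1, which encodes a microRNA Argonaute, fell from 808 ± 50.3 to 323 ± 19.1 reads (−1.32, SE 0.16, adjusted p = 0.000353), a value that is uncertain because alg-2 is a close copy. The list median was −0.23 (camera adjusted p = 0.0424, and adjusted p = 0.808 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0591), control replicate 2 (0.0879), P granule replicate 2 (0.0543) or csr-1 replicate 3 (0.506, median −0.07), and with a filter of at least 5 CPM (0.166). Of 20 histone genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.000492, and adjusted p = 0.712 with an estimated correlation); without the low-value filter the median was 0.35 and the call was lost (adjusted p = 0.0651). his-48 (1.68, SE 0.29) and his-59 (1.87, SE 0.36) rose, and his-32 fell (−1.91, SE 0.45), all uncertain because histone genes are near-identical. The libraries hold poly(A) RNA, so histone transcripts without a poly(A) tail were not measured. Of 34 meiosis genes, 5 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.08, camera adjusted p = 0.368, and without csr-1 replicate 3 adjusted p = 0.0415, or adjusted p = 0.637 with an estimated correlation). htp-1, which encodes a protein of the meiotic chromosome axis, rose (1.27, SE 0.19, adjusted p = 0.00142; uncertain, since htp-2 is a close copy), and pch-2, a meiotic checkpoint gene, fell (−0.73, SE 0.15, adjusted p = 0.00702). Of 30 genes of germline proliferation, 6 rose and 1 fell (6 and 3 adjusted over the list alone; median −0.05, mean 0.05, camera adjusted p = 0.83). They included hcp-3, the gene of the centromeric histone (3131 ± 145 to 8617 ± 771 reads, 1.46, SE 0.18, adjusted p = 0.000391), and cdk-1, the mitotic kinase gene (1.31, SE 0.17, adjusted p = 0.000664). Of 11 genes of germline apoptosis, egl-1, the trigger of programmed cell death (2.34, SE 0.42, adjusted p = 0.00393), and cep-1, the worm p53 gene (0.61, SE 0.18), rose. In the same list lip-1 (−0.98, SE 0.17, adjusted p = 0.00289), gla-3 (−0.66, SE 0.13) and clk-2 (−0.59, SE 0.18) fell, the same counts as adjusted over the list alone (median −0.17, mean 0.02, camera adjusted p = 0.45).

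Among markers of tissues outside the germline, cuticle, muscle and intestine genes were seldom called, where 1677 of all 11345 tested genes were. fry's mixed test passed for the neuronal (adjusted p = 4.59e-09) and stress (0.0153) lists. It did not pass for the cuticle (0.348), muscle (0.436), intestine (0.707), sheath and spermatheca (0.344) or ribosomal (0.268) lists. Of 18 neuronal markers, unc-31 and cat-2 (2.38, SE 0.58) rose and syd-2 fell (−1.65, SE 0.32, adjusted p = 0.00521), the same as adjusted over the list alone, with a median of −0.01 and a mean of 0.16 (camera adjusted p = 0.967). Of 98 cuticle and hypodermis genes, col-83 rose (2.44, SE 0.45, adjusted p = 0.00414) and dpy-10 fell (−1.58, SE 0.31, adjusted p = 0.00586), again the same adjusted over the list alone (median 0.001, mean −0.10, camera adjusted p = 0.83). Without the 3 libraries named orig the cuticle median was 0.65 and the list passed (adjusted p = 0.00642, and adjusted p = 0.83 with an estimated correlation). None of the 21 muscle markers (median 0.09, mean −0.04, camera adjusted p = 0.83) or 17 intestine markers (median −0.10, camera adjusted p = 0.762) passed limma's test over all genes or adjusted over the list alone. In each list 1 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. Of 14 genes of the gonadal sheath and spermatheca, fos-1 fell (−1.31, SE 0.32, adjusted p = 0.0167; 0.0546 without control replicate 2 and 0.0546 without the 3 orig libraries; median of the list −0.05, camera adjusted p = 0.5). The mean log2 level of this list was 7.01 to 7.36 in the 3 libraries named orig, 1 in each group, and 7.99 to 8.41 in all the others. Of 14 stress response genes, the chaperone genes hsp-3 (−0.78, SE 0.18, adjusted p = 0.0122) and hsp-6 (−0.60, SE 0.17, adjusted p = 0.0336) fell. The call on hsp-6 was lost without control replicate orig, 1 or 2 or csr-1 replicate 1, 2 or 3 (adjusted p between 0.061 and 0.0946), or without the 3 orig libraries (0.0803). Both of these counts were the same adjusted over the list alone, and the stress list did not pass as a whole (median −0.10, camera adjusted p = 0.245). Of 78 ribosomal protein genes, rpl-41.1 (0.89, SE 0.21, adjusted p = 0.0145) and rpl-24.2 (0.50, SE 0.14, adjusted p = 0.0326) rose and rpl-9 fell (−0.61, SE 0.18). Adjusted over the list alone 0 were called, where edgeR called 3 and DESeq2 4 over all genes and 13 had an unadjusted p under 0.05. The call on rpl-24.2 was lost without any control replicate or without csr-1 replicate 1, 2 or 3 (adjusted p between 0.0542 and 0.105), and without the low-value filter (0.0582). The ribosomal median was −0.26 (camera adjusted p = 0.000786, and adjusted p = 0.859 with an estimated correlation). Without csr-1 replicate orig it was −0.08 and not called (adjusted p = 0.41), and without the 3 orig libraries −0.04 (adjusted p = 0.852).

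Genes on chromosome X, which is largely silent in the germline, were lower under csr-1 RNAi as a group. Of 1318 measured X-linked genes, 26 rose and 202 fell, or 28 and 218 adjusted over the list alone. Their median log2 fold change was −0.32 (camera adjusted p = 8.5e-07, and adjusted p = 0.0793 with an estimated correlation). C17H11.2 fell from 525 ± 110 to 112 ± 18.7 reads (−2.21, SE 0.20, adjusted p = 6.11e-05), and F59C12.4 rose from 139 ± 23.7 to 705 ± 268 (2.28, SE 0.25, adjusted p = 0.000221). The mean log2 level of the X-linked genes was 6.41 ± 0.06 in the control and 6.11 ± 0.08 under csr-1 RNAi (SD, n = 4), with all 4 csr-1 libraries below all 4 controls. The exact permutation p of 0.0286 is the smallest that 4 libraries against 4 allow, and it became 0.315 after adjustment over 22 lists. The autosomal genes averaged 8.12 ± 0.11 in the control and 8.28 ± 0.13 under csr-1 RNAi (exact permutation p = 0.143, n = 4). Under P granule RNAi the X median was −0.06 (camera adjusted p = 0.207), and it passed at −0.12 without P granule replicate 3 (adjusted p = 0.042, and adjusted p = 0.629 with an estimated correlation). None of its X-linked genes passed limma's test over all genes or adjusted over the list alone (109 at an unadjusted p under 0.05; edgeR 0, DESeq2 7).

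**Figure D3:**
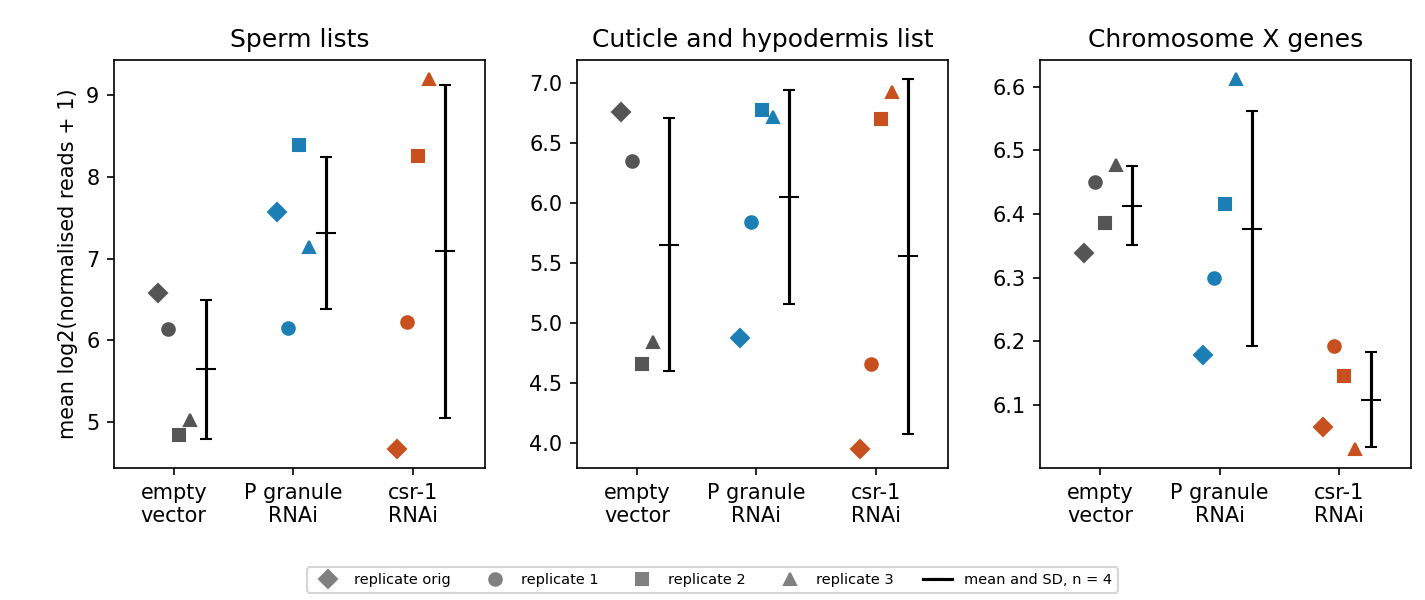
Mean log2(normalised reads + 1) of the sperm genes, of the cuticle and hypodermis genes and of the chromosome X genes in each library, by group; symbols give the replicate and bars the mean and SD of 4 libraries. The X level was 6.11 under csr-1 RNAi against 6.41 in the control, and the sperm level ranged from 4.67 to 9.20 in the csr-1 libraries.

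The comparison of P granule RNAi with the empty vector asks what loss of these granules does to germline transcripts. limma called 7 genes, 3 higher and 4 lower, with 1560 genes at an unadjusted p under 0.05. The 4 lower genes were pgl-1, pgl-3 and glh-4, which the RNAi targeted, and T12F5.2, which fell from 1169 ± 128 to 344 ± 115 reads (log2 fold change −1.82, SE 0.22, adjusted p = 0.00487) and is the next gene downstream of glh-4 on the same strand. timm-17B.2, which encodes a component of mitochondrial protein import, rose from 750 ± 143 to 2372 ± 573 reads (1.65, SE 0.22, adjusted p = 0.0114). Its call was lost without control replicate orig (adjusted p = 0.0626), 1 (0.056) or 3 (0.0618), or without P granule replicate orig (0.063) or 3 (0.0529). With the replicate number as a block it was lost as well (0.0604). The other 2 higher genes, Y45F10C.6 (12.3 ± 1.95 to 88.5 ± 11.4 reads, 2.76, SE 0.30, adjusted p = 0.00189) and Y76B12C.8 (13.9 ± 1.79 to 67.0 ± 9.60, 2.19, SE 0.27, adjusted p = 0.00615), were named after their values were seen. DESeq2 called 76 genes and edgeR 7, and without the 3 libraries named orig limma called 4, T12F5.2 (adjusted p = 0.136), timm-17B.2 (0.163) and Y76B12C.8 (0.136) not among them. Without csr-1 replicate 3, which enters through the shared estimate of the spread, limma called 200, 44 higher and 156 lower.

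The sperm lists were higher under P granule RNAi as lists, although 0 of their 84 genes passed limma's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 20 of the 84, and edgeR and DESeq2 called 0. All 28 major sperm protein genes had positive fold changes (median 2.07, camera adjusted p = 1e-08, and adjusted p = 0.785 with an estimated correlation). So did all 24 genes of the small sperm protein families (median 2.17, camera adjusted p = 7.48e-09, and adjusted p = 0.723 with an estimated correlation) and 29 of 32 genes of sperm function (median 1.15, camera adjusted p = 0.000316, and adjusted p = 0.785 with an estimated correlation). The estimated correlation was taken over all 3 groups, the widely spread csr-1 libraries included. The mean log2 level of the 84 genes was 7.32 ± 0.93 under P granule RNAi and 5.65 ± 0.85 in the control (SD, n = 4), with 3 of 4 libraries above all controls (two-sided exact permutation p = 0.0571, adjusted 0.157 over 22 lists). For the small families alone all 4 libraries lay above all controls (7.91 ± 0.86 against 5.84 ± 0.86, n = 4, exact permutation p = 0.0286, adjusted 0.157). The cuticle and hypodermis genes averaged 6.05 ± 0.89 under P granule RNAi and 5.65 ± 1.06 in the control (n = 4, exact permutation p = 0.571), with a list median of 0.46 (camera adjusted p = 0.0736). The cuticle list passed camera without control replicate orig (median 0.68, adjusted p = 0.00205) or 1 (0.68, adjusted p = 0.00391), without P granule replicate orig (0.93, adjusted p = 0.00033) or 1 (0.51, adjusted p = 0.0387), and without csr-1 replicate 1 (0.46, adjusted p = 0.0497). Without all 3 libraries named orig its median was 1.22 (adjusted p = 9.96e-08, and adjusted p = 0.645 with an estimated correlation). It also passed with a filter of at least 5 CPM (0.63, adjusted p = 0.00377) and with TMM factors (0.43, adjusted p = 0.0361). With an estimated correlation the cuticle list did not pass in any of these settings (adjusted p = 0.645 to 0.89, and 0.882 with all libraries).

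Several germline lists were slightly lower under P granule RNAi by camera with its preset correlation, and none of these calls held with an estimated correlation. The meiosis list had a median of −0.30 (34 genes, camera adjusted p = 7.86e-06, and adjusted p = 0.184 with an estimated correlation), with all 4 libraries below all controls (10.91 ± 0.06 against 11.17 ± 0.06, n = 4, exact permutation p = 0.0286, adjusted 0.157). him-17 (−0.63, SE 0.14) and him-3, which encodes a protein of the chromosome axis (−0.65, SE 0.14), passed adjusted over the list alone. The small RNA list had a median of −0.36 (47 genes, camera adjusted p = 6.32e-09, and adjusted p = 0.535 with an estimated correlation), and sid-1, which encodes a double-stranded RNA channel (−0.82, SE 0.19), and rde-2 (−0.63, SE 0.14) passed adjusted over the list alone. The P granule components outside the targets had a median of −0.25 (27 genes, camera adjusted p = 5.36e-05, and adjusted p = 0.587 with an estimated correlation). Poly(A) transcripts of histone genes were higher, with a median of 0.55 (20 genes, camera adjusted p = 3.29e-05, and adjusted p = 0.587 with an estimated correlation), as were those of ribosomal protein genes, with a median of 0.25 (78 genes, camera adjusted p = 5.98e-06, and adjusted p = 0.808 with an estimated correlation). Among the sex determination genes (median −0.17, camera adjusted p = 0.0245, and adjusted p = 0.785 with an estimated correlation), mag-1 was higher and daz-1, gld-3, nos-3 and laf-1 lower adjusted over the list alone. That list was not called without control replicate 1 (adjusted p = 0.0521), control replicate 2 (0.0762) or P granule replicate 3 (0.111), or with a filter of at least 5 CPM (0.143). In each of these lists 0 genes passed limma's test over all genes. DESeq2 called 2 genes each in the meiosis and small RNA lists and 0 in the others, edgeR called 0, and the genes at an unadjusted p under 0.05 numbered 14, 16, 9, 5, 9 and 7 in the order given.

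The remaining lists under P granule RNAi had 0 genes called by limma, edgeR or DESeq2, and 0 adjusted over the list alone. The proliferation list had a median of −0.07 (5 genes at an unadjusted p under 0.05, camera adjusted p = 0.0424, and adjusted p = 0.796 with an estimated correlation). The proliferation call was lost without control replicate 2 (adjusted p = 0.175) or 3 (0.128), P granule replicate orig (0.092), 2 (0.119) or 3 (0.273), or csr-1 replicate orig (0.0524) or 3 (0.0747), and with a filter of at least 5 CPM (0.266). The muscle list had a median of 0.59 (0 genes, camera adjusted p = 0.0441, and adjusted p = 0.785 with an estimated correlation). The muscle call was lost without control replicate orig (0.0579), 2 (0.134) or 3 (0.217) or P granule replicate 2 (0.176) or 3 (0.216). The intestine list had a median of −0.61 (1 gene, camera adjusted p = 0.0372, and adjusted p = 0.808 with an estimated correlation). Its median was 0.07 without P granule replicate orig, and its call was also lost without control replicate 1 (0.166) or 3 (0.146), P granule replicate 1 (0.0606) or csr-1 replicate 3 (0.0879), without the 3 orig libraries (0.236) and with a filter of at least 5 CPM (0.247). The replicate number as a block removed the intestine call too (0.059). The apoptosis list had a median of −0.22 (2 genes, camera adjusted p = 0.0424, and adjusted p = 0.587 with an estimated correlation). The apoptosis call was lost without control replicate 2 (0.0753) or 3 (0.0962), P granule replicate 2 (0.1) or 3 (0.111), or csr-1 replicate orig (0.053) or 3 (0.079), without the 3 orig libraries (0.0555) and with a filter of at least 5 CPM (0.193). With the replicate number as a block it was lost as well (0.0608). The oogenesis list had a median of −0.05 (4 genes, camera adjusted p = 0.148), which passed without P granule replicate 1 (−0.20, adjusted p = 0.00011, and adjusted p = 0.485 with an estimated correlation). The stress list had a median of −0.19 (3 genes, camera adjusted p = 0.0857) and also passed without P granule replicate 1 (−0.28, adjusted p = 0.0279) and with a filter of at least 5 CPM (−0.21, adjusted p = 0.0438). With an estimated correlation it did not pass there (adjusted p = 0.438 and 0.83). Neuronal markers (median 0.21, 1 gene, camera adjusted p = 0.687) and sheath and spermatheca genes (median 0.06, mean −0.03, 1 gene, camera adjusted p = 0.45) did not pass.

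**Figure D4:**
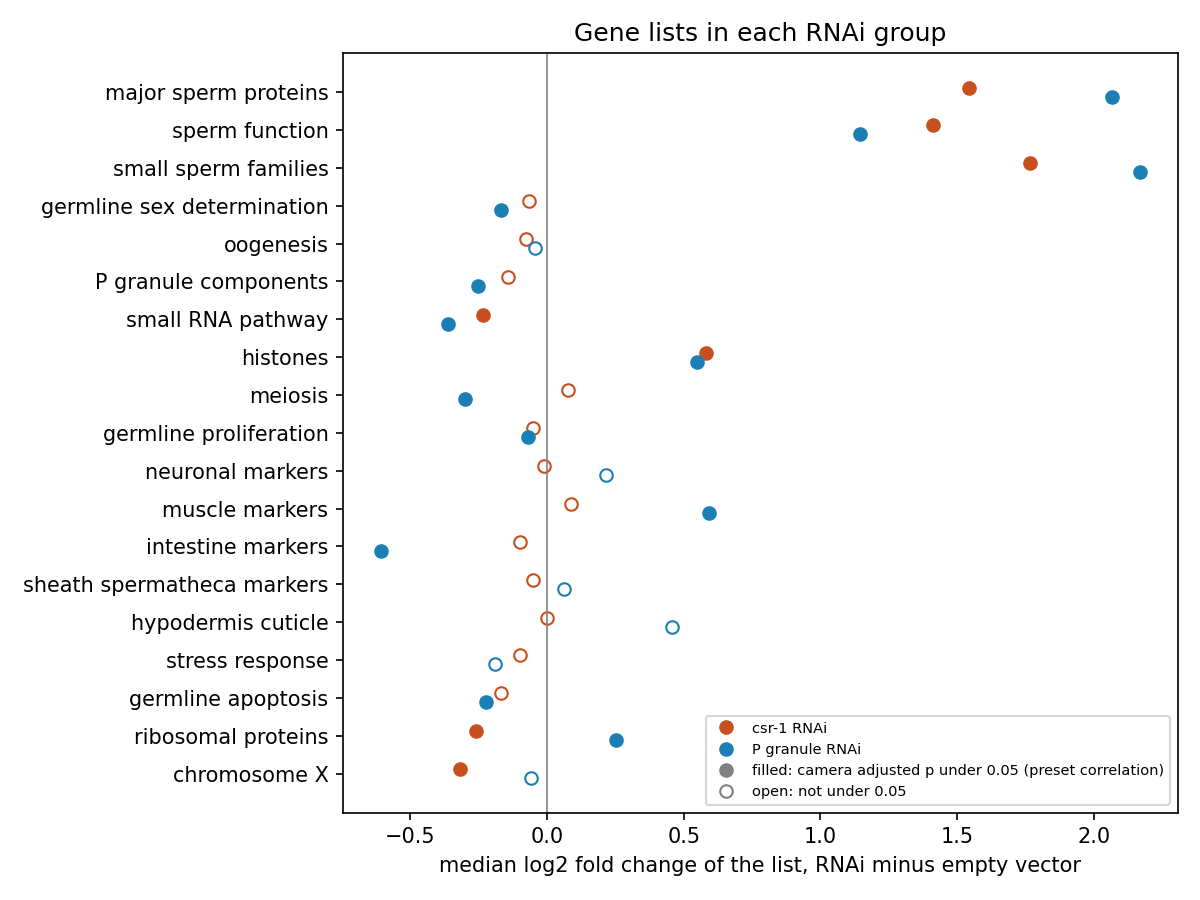
Median log2 fold change of each gene list (horizontal axis) under csr-1 RNAi and under P granule RNAi, each against the empty vector; filled points passed camera with the preset correlation. The medians of the major sperm proteins were 1.54 and 2.07, and those of chromosome X −0.32 and −0.06.

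The direct comparison of csr-1 RNAi with P granule RNAi tests whether the treatments differ, without the shared control. It called 1080 genes, 596 higher and 484 lower under csr-1 RNAi (limma). Chance was not excluded for this count, as set out under the results flagged for a closer look. glr-2 (log2 fold change 4.46, SE 0.54), nhr-11 (4.24, SE 0.25), unc-31 (4.10, SE 0.45), droe-4 (3.86, SE 0.40) and cutl-23 (3.77, SE 0.42) were the 5 largest differences in favour of csr-1 RNAi, at adjusted p between 2.05e-06 and 0.000447. bath-13 (−3.41, SE 0.39), H11L12.1 (−3.18, SE 0.35), cutl-10 (−2.87, SE 0.65), linc-29 (−2.74, SE 0.37) and fbxb-97 (−2.65, SE 0.33) were the 5 largest in favour of P granule RNAi, with adjusted p between 0.000262 and 0.0161. The call on cutl-10 was lost with only the 2 groups compared (adjusted p = 0.0564) and without the 3 orig libraries (0.0913). In the sperm lists only spe-6 differed (1.42, SE 0.16, adjusted p = 0.000299), also adjusted over the list alone. The list medians of −0.37, 0.14 and −0.35 for major sperm proteins, sperm function and small families did not pass (camera adjusted p = 0.225, 0.225 and 0.542). Of the meiosis genes 9 were higher and 1 lower under csr-1 RNAi (16 and 1 adjusted over the list alone; median 0.35, camera adjusted p = 4.07e-06, and adjusted p = 0.0782 with an estimated correlation). The X-linked genes had a median of −0.29, with 15 higher and 118 lower (15 and 120 adjusted over the list alone; camera adjusted p = 6.45e-06, and adjusted p = 0.0782 with an estimated correlation). The ribosomal protein genes had a median of −0.53 (camera adjusted p = 3.02e-13, and adjusted p = 0.96 with an estimated correlation). The number of genes was 717 without P granule replicate 2, 688 without P granule replicate 3, 718 without csr-1 replicate orig, 535 without csr-1 replicate 1, 585 without csr-1 replicate 2 and 1952 without csr-1 replicate 3. It was 515 when the control libraries were left out of the model.

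Both RNAi comparisons called 3 genes in common. T12F5.2 was lower in both (−0.79 under csr-1 RNAi and −1.82 under P granule RNAi), and timm-17B.2 (−0.99 and 1.65) and glh-4 (1.22 and −2.22) went in opposite directions. Without any of the control replicates, or without csr-1 replicate 1 or 2, 0 genes were called in the same direction in both; without csr-1 replicate 3 there were 31, and DESeq2 gave 35. Independent lists of these sizes would share 0.209 genes higher in both and 0.312 lower in both. The fold changes of all tested genes correlated across genes, which are not independent replicates (Pearson r = 0.64). Unchanged groups simulated against the same controls gave a median r of 0.53 (central 95% of the simulations −0.50 to 0.93). This range holds the observed r, but it is too wide to tell how much of r the shared controls gave. The covariance was 0.334 against a simulated median of 0.098 (central 95% −0.115 to 0.501). With the 4 controls split so that each comparison had its own 2, the 6 splits gave r between 0.30 and 0.56 and a covariance between 0.201 and 0.294, and 0 genes were called in the same direction in both.

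The authors' deposited tables held 982 genes at an adjusted p under 0.05 for csr-1 RNAi, 805 higher and 177 lower, and 104 for P granule RNAi, 89 higher and 15 lower. Control replicate orig was the highest control for 94 of the 177 lower genes and for 12 of the 15. Of the 94 sperm list genes in the files, 62 were among those higher under csr-1 RNAi and 39 among those higher under P granule RNAi in the authors' deposited tables. Of their 982 genes, 838 were tested here and 345 were also called by limma, all 345 in the same direction. Of their 104 genes, 94 were tested and 5 were called, all in the same direction. Of the 982 genes in the authors' deposited table for csr-1 RNAi 420 had, and of the 104 in the other 45 had, all 4 RNAi libraries beyond all 4 controls. Chance gives 2.86% for unselected genes, but these genes were selected on the same libraries, so that share is no measure for them. DESeq2 on the recovered reads called 745 of the 982 and 11 of the 104.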

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

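The tests of oocyte content and of the shared variation of sperm and cuticle genes, the fits of the cuticle covariate with libraries left out and the comparison of sperm genes with other cell types were chosen only after the result was seen.

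Of 140 groups of 4 libraries tested for a library far from the others, 5 were past the 95% critical value of Dixon's test, where chance gives about 1 in 20. Control replicate 3 was far below the other controls for glh-4 (5344 reads), fos-1 (75.1 reads) and hsp-6 (26305 reads). Control replicate orig was far above the others for spe-47 (37.4 reads), and P granule replicate orig for Y45F10C.6 (105.5 reads). A signal outside the gene values also differed: reads with no unique alignment made up 2.551% ± 0.192 of the csr-1 libraries and 2.131% ± 0.077 of the controls (SD, n = 4, two-sided exact permutation p = 0.0286, the smallest possible), with all 4 csr-1 libraries above all controls. The cause was not tested.

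Other splits of the 8 libraries into 4 and 4 tested whether the counts of genes can arise by chance. For csr-1 RNAi the real split gave 1677 genes and the highest of the other splits 33, so 1 of 35 reached that count. That is the smallest share possible, and it argues against chance. For P granule RNAi the real split gave 7 genes and the highest other 0, so again 1 of 35 reached it. This count cannot decide on chance for the genes beyond the targets. Of the 7 genes 3 were RNAi targets, for which the real split shows only the knockdown, and T12F5.2 is the next gene downstream of glh-4. With these 4 genes left out the real split gave 3 genes and the highest other 0, so 1 of 35 reached it, the smallest share possible. The count is no test of the other genes one by one. Between the RNAi groups 2 of 35 splits reached the real count of 1080, so chance was not excluded for that comparison. The higher count, 1506, came from setting P granule replicate orig and csr-1 replicates orig, 1 and 2 against the rest, and another, with P granule replicates orig and 2 and csr-1 replicates 2 and 3 on 1 side, gave 784, which points to a structure of the samples that the groups do not explain. A swapped pair of libraries is argued against by csr-1, pgl-1, pgl-3 and glh-4, which were low in all 4 libraries of the group whose RNAi targeted them; glh-1 was below all controls in 3 of 4.

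The mean log2 level of the sperm lists was 1.67 (SE 0.98) higher under P granule RNAi and 1.44 (SE 0.98) higher under csr-1 RNAi, differences that did not pass exact permutation (p = 0.0571 and 0.314, adjusted 0.157 and 0.768), and no camera call on these lists held with an estimated correlation (adjusted p = 0.723 to 0.81). Both SEs come from 1 fit with a spread shared by all 3 groups. The SDs were 0.85 in the control, 0.93 under P granule RNAi and 2.04 under csr-1 RNAi. So the csr-1 libraries widened the SE for P granule RNAi. The estimated correlation was also taken over all 3 groups. Within groups the sperm level followed that of cuticle genes (r = 0.84), which meets the bound set for a variation shared between libraries, such as the stage of the animals. Autosomal genes followed nearly the same order between libraries, so the relation is not particular to cuticle genes or to stage. With the cuticle level as a covariate the csr-1 difference was 1.54 (SE 0.57), above 50% of the original (0.72) by more than its SE. With all libraries the mean cuticle level was 5.56 under csr-1 RNAi and 5.65 in the control, so the covariate could hardly lower the csr-1 difference. The fit therefore cannot exclude a difference in stage. The shared variation was neither taken as the explanation for both groups nor excluded, a verdict reached after r was seen. The csr-1 value depends on the orig libraries. Without all 3 the value was 1.66 (SE 0.47) against 1.28, and without control replicate orig alone 1.48 (SE 0.66) against 0.88, both above by less than the SE. There the cuticle median without all 3 was 0.65 (camera adjusted p = 0.00642, and adjusted p = 0.83 with an estimated correlation). For P granule RNAi the value with the covariate was 1.28 (SE 0.57), above 50% (0.83) by less than its SE. It was 0.60 (SE 0.51) without the orig libraries and 0.63 (SE 0.43) without P granule replicate orig, under 50% (0.95 and 0.79), and 1.54 (SE 0.59) without P granule replicate 3, above 0.86 by more than its SE. So an effect of the RNAi and of the libraries' stage cannot be told apart there with 4 libraries per group. Fewer oocytes were not excluded either. The lower median of the oogenesis list was −0.075, above the −0.142 set as a bound, but without P granule replicate 1 it was −0.202, and within groups this list went against the sperm genes (r = −0.55, adjusted permutation p = 0.0394). The −0.5 behind that bound was assumed, and these genes have high levels, so a small loss of oocytes would hardly move them. Sperm genes minus the mean of intestine, muscle, neuronal and sheath markers differed by 1.72 (SE 1.01) and 1.48 (SE 1.01), which did not decide it. An effect of the RNAi on sperm genes, carry-over from the proximal gonad, fewer oocytes and a difference in stage remain open for both groups.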

How the results depend on the processing

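The alternatives were chosen before the data were examined, except limma with TMM factors, the pseudocounts and the omission of the libraries named orig. Those were chosen after seeing the data. The edgeR test with TMM factors had been planned as the main test, and limma took its place after the deposited values were seen. For csr-1 RNAi the count of 1677 genes was between 1189 and 2502 under all whole-data alternatives except an absolute log2 fold change of at least 1, which left 839 by its construction, and between 931 and 2110 with 1 library left out. For P granule RNAi the count of 7 was 76 with DESeq2 (41 higher, 35 lower), 4 without the 3 orig libraries, and 6 to 200 with 1 library left out. Between the RNAi groups the count of 1080 was 515 with only the groups compared, 572 with an absolute log2 fold change of at least 1, 389 without the orig libraries, and 535 to 1952 with 1 library left out. The replicate number as a block gave 2082, 6 and 1284 genes; it is not shown to be a pairing, since same-numbered libraries correlated at −0.47 to 0.66 and 0, 2 and 2 of 4 numbers correlated best with their own, but the 3 orig libraries had the most reads of their groups and the lowest levels of sheath and spermatheca genes (7.01 to 7.36 against 7.99 to 8.41), so a batch of their own is not excluded. Under the block timm-17B.2 (adjusted p = 0.0604) and the intestine (0.059) and apoptosis (0.0608) lists under P granule RNAi were not called. The cuticle list was called there at the preset correlation (0.0193). Without the block and with an estimated correlation its adjusted p was 0.882. No other call on a list or named gene changed under the block. The genes called in the same direction in both RNAi comparisons numbered 1, and 35 with DESeq2, 0 without the orig libraries, 0 with the fold minimum, 0 with split controls, and 0 to 31 with 1 library left out. The medians of the sperm lists stayed positive under every alternative. With an estimated correlation and with fry's test for 1 direction no call held (fry adjusted p = 0.291 to 0.503). fry's mixed test passed for sperm function under csr-1 RNAi (adjusted p = 0.00685) and for no other sperm list in either comparison. The medians there were unchanged, at 1.54, 1.41 and 1.77 for major sperm proteins, sperm function and small families under csr-1 RNAi. Under P granule RNAi they were 2.07, 1.15 and 2.17. With 1 library left out these medians ranged from 0.64 to 2.604, 0.82 to 1.96 and 0.996 to 2.64, and from 1.68 to 2.42, 0.77 to 1.73 and 1.81 to 2.56. The X median under csr-1 RNAi, −0.32, lost its call with an estimated correlation and not with fry, and ranged from −0.38 to −0.27 with 1 library left out. Under P granule RNAi it ranged from −0.117 to −0.016. The intestine median under P granule RNAi reversed to 0.074 without replicate orig and ranged from −1.224 to 0.074 with 1 library left out. Among the other lists 66 values lost a call, 14 gained 1, 591 did neither and 1 more, the reversed intestine median, also lost its call, and among named genes 38 lost a call, 0 gained 1 and 1505 did neither. The authors' counts of 982 and 104 did not change with the fold minimum. The cause was not tested for any of these except where fewer libraries or a fold minimum made the change. At 18.4 to 31.9 M reads, simulated 2-fold changes, with genes drawn independently, were recovered in 35% and 31% of genes. The effect of depth itself was not tested.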

Other observations

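The test of neuronal carry-over and the limit of 10 reads in the control were chosen only after the result was seen; the other tests here were set before theirs.

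There were 179 genes that rose at least 4-fold under csr-1 RNAi, with a median control level of 6.6 reads against 272.6 for all tested genes, and the 76 that fell at least 4-fold had a median control level of 84.6 reads. The low-value filter fixes part of this contrast, since a gene low in the controls was tested only where other libraries were higher, and 116 of the 179 had a control mean under 10 reads. Among the 10277 tested of 10345 genes with a control mean of at least 10 reads, 63 rose at least 4-fold (median control level 19.3 reads against 469.6 for all 10277) and 75 fell (85.1 reads). The control level also enters the fold change, so these medians are given as values only. None of the 179 was in the sperm lists and 6 were on chromosome X. nhr-11, rol-3, glr-2 and unc-31, whose known roles lie outside the germline, were among them. Carry-over of neurons may be considered, but the other 17 neuronal markers had a median log2 fold change of −0.024 (SD of their library means 0.375) where the explanation needs at least 2, which argues against it. Reads running on from an adjacent upstream neighbour on the same strand that rose are argued against too. Such a neighbour was found for 6 of 176 of these genes and 333 of 10668 others (odds ratio 1.1, 95% interval 0.39 to 2.46, Fisher's exact p = 0.825). Neighbours on the other strand, whose reads could not be told apart here, were not tested. A gain of RNA from genes kept low in the germline when csr-1 is reduced stays a hypothesis, for which no further test was made.

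The lower level of X-linked genes under csr-1 RNAi was set against technical explanations. X-linked genes have low levels in the germline, but their median of −0.32 lay at percentile 0 of 10000 lists of autosomal genes matched on mean level, whose median was 0.128 (0.086 to 0.177). The matched lists do not allow for genes that vary together. Less somatic tissue in the csr-1 libraries could lower X-linked genes that soma expresses. The 355 X-linked genes above the median level also lay lower than matched autosomal lists, by −0.401 (5 rose and 89 fell). Which of these genes soma expresses was not determined, so this comparison cannot exclude less somatic tissue. The neuronal, muscle, intestine, sheath and cuticle lists had medians between −0.10 and 0.09 under csr-1 RNAi. A response of X-linked genes to csr-1 RNAi may be a biological one, as a hypothesis found and tested on the same libraries. It did not pass camera with an estimated correlation (adjusted p = 0.0793) with all libraries, and passed without csr-1 replicate 1 (adjusted p = 0.0351).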
